A study of Saccharomyces cerevisiae with 17 samples.

How the data were processed

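The series holds 17 libraries of Saccharomyces cerevisiae: 8 of RNA, 2 for each of 4 genotypes, and 9 of genomic DNA, 6 from chromatin immunoprecipitation and 3 inputs. The immunoprecipitation and input libraries were not analysed here. RNA was depleted of rRNA and made into stranded libraries, per the labels' protocols. The submitters' processing notes name CASAVA, TopHat2 2.0.14 and the genome build sacCer3 for the RNA libraries, and CASAVA, Bowtie 0.12.8 and MACS2 for the DNA libraries. The tool that computed RPKM, the gene models, the use of strand and the treatment of reads that map to several places are not given in the sources used here.

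The deposited table gives RPKM, reads scaled by gene length and by library size, in 4 value columns, which are the authors' averages over the libraries of each genotype per the file headers. The read total used as library size (mapped reads, or reads in genes) is not given in the sources used here. RPKM of a gene depends on the other genes: where a few abundant RNAs take more of the reads, the values of all other genes are lower. Copies that share reads, such as CUP1-1 and CUP1-2, carry equal values, and 28 rows share all 4 values with another row. The lowest value in the table is 1.00, so every gene listed has an RPKM of at least 1 in every genotype, and a gene below that in any genotype has no row. The most extreme ratios, low and high, can be missing for that reason. A gene below 1 in wild type and high in a mutant has no row. Read depth cannot be recovered from averages of RPKM, so the depth per library and the counting error of each value are unknown.

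Of 5328 rows, 2 carry the name R, which names no gene; they hold 0.0032% of the wild-type RPKM sum and were left out, which leaves 5326 genes. Another 3 lines of the table had been emptied for this work and are not among the 5328; which genes they held is unknown here. Gene names, coordinates and lengths came from a RefSeq gene table of the R64 assembly, the same build as sacCer3, by systematic name: 5176 names matched and 150 did not, and the latter kept the name in the table.

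The planned tests, limma on 8 libraries and camera on gene lists, needed a column per library. A plan for averaged columns had been written before the data were examined and was followed: log2((mutant + 1)/(wild type + 1)) per gene with a pseudocount of 1, the count of genes beyond 2-fold (at least 2-fold higher or lower) among genes with a mean RPKM of at least 10 over the 4 genotypes, and no test or p-value. Such ratios understate the change of genes of low RPKM. Each list median was placed among 10000 random lists of the same size drawn from genes in the same 20 bins of mean RPKM; this describes these libraries and is not a test between genotypes. Members of the list were left out of the genes drawn unless a bin held too few others. Giving log2 ratios relative to the median gene of the comparison was chosen after the shift of the median had been seen, and counts are printed on both scales.

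Lists were fixed before the data were examined: the altered genes, the Set2 and Rpd3S pathway, NuA4, histones, spliceosome proteins, intron-containing genes outside the ribosomal proteins, meiosis, stress-induced genes, ribosome biogenesis, the phosphate and galactose regulons, sulfur and methionine metabolism, Gcn4 targets, oxidative phosphorylation, glucose-repressed carbon metabolism, glycolysis, genes with internal promoters used in set2 mutants, auxotrophic markers, MATa and MATalpha genes, cytosolic and mitochondrial ribosomal proteins, small nuclear and nucleolar RNAs, seripauperins, COS genes and genes within 20 kb of a chromosome end. The rule for named genes was also fixed then: the altered genes; the 8 highest and 8 lowest ratios of each mutant to wild type among genes compared; per list up to 4 members beyond 2-fold with the largest ratios, or up to 2 as values where none passed; the 5 highest and 5 lowest between mutants; and 8 per direction among genes beyond 2-fold in all 3 mutants. The neighbours of SOP4 and the follow-up genes of the closing section were chosen after their values or those of the pattern had been seen.

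For genes shared by mutants, chance was simulated by adding noise of equal variance to 4 unchanged columns, 100 times. That variance, 0.0598, came from the pair of mutants that differed least and assumes the same noise in every genotype. Overlaps were given for independent lists of the observed sizes and, from the same kind of simulation, both beyond 2-fold and with as many genes taken per mutant as observed. The simulated overlaps and the list values over all listed members were added after seeing the data.

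Alternatives were a pseudocount of 0.1 or 5, a mean RPKM of at least 1, centring on the median log2 ratio, quantile normalization, and RPKM without small RNA genes rescaled to the remaining sum. Leaving out rows of repeated values and leaving out rows without a match in the reference were added after seeing the data. The calculations were tested on simulated data: for the set2 deletion against wild type, over 4146 genes with 200 changed 4-fold and noise of SD 0.2 on the log2 scale, 100% of changed genes were beyond 2-fold and 0 unchanged genes were. The changed genes were drawn from those well above the minimum mean RPKM. The noise was equal at every level and the median was not shifted. This checks the calculation and does not measure the error of the counts reported here. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.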

Results

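Steady-state RNA was measured by sequencing in haploid budding yeast (Saccharomyces cerevisiae) of the BY4741 background, a MATa laboratory strain, grown to mid-log phase in rich glucose medium (YPD) at 30 °C. The 4 genotypes were wild type, a deletion of set2, a deletion of eaf3 and the histone mutant H3K36A. Set2 is the methyltransferase of lysine 36 on histone H3, H3K36A replaces that lysine with alanine, and Eaf3 is a chromodomain protein that binds the methylated residue. The design held 2 biological replicate libraries of total RNA depleted of rRNA per genotype, 8 in all. The values used are the authors' mean RPKM of each genotype, so no measure of the spread between replicates exists here, no difference was tested, and every value below is the authors' mean. The number of reads behind each mean is unknown. The table names 5326 genes, of which 3657 had a mean RPKM of at least 10 over the 4 genotypes and were compared. No value for SET2, EAF3, HHT1 or HHT2 was used here, because none of these 4 genes has a row in the table as used here, and the genotypes were therefore not checked on the altered genes themselves. The 9 libraries of chromatin immunoprecipitation and input DNA were not analysed here.

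Most genes had a lower RPKM in each mutant than in wild type. The median log2 ratio to wild type was -0.23 in the set2 deletion, -0.32 in H3K36A and -0.36 in the eaf3 deletion. The median RPKM over all listed genes was 23.0 in wild type, 17.5 in the set2 deletion, 16.0 in H3K36A and 15.4 in the eaf3 deletion. Small RNA genes are here those whose names start with snR, together with SCR1, RPR1 and NME1 where listed. They took 22.7% of the RPKM sum in wild type against 27.1%, 29.9% and 28.2% in the mutants, in the same order. Weighted by gene length, which is closer to a share of reads, they took 8.79% against 11.3%, 12.7% and 11.6%. From the quartile of genes with the lowest mean RPKM to the quartile with the highest, the median log2 ratio went from -0.42 to -0.01 in the set2 deletion, from -0.56 to -0.05 in H3K36A and from -0.59 to -0.14 in the eaf3 deletion. Ordered by wild-type RPKM alone, the medians of the set2 deletion were -0.25, -0.34, -0.25 and -0.06 from the lowest quartile to the highest, those of H3K36A -0.24, -0.48, -0.39 and -0.17, and those of the eaf3 deletion -0.35, -0.49, -0.38 and -0.21. Spearman's rho across genes with wild-type RPKM was 0.14, 0.01 and 0.08, against 0.38, 0.27 and 0.33 with mean RPKM. Neither value measures the dependence on expression level alone. Wild-type RPKM is the denominator of the ratio, mean RPKM holds the mutant values, and the minimum mean RPKM also uses the mutant values. The ratio also depended on gene length, from -0.10 in the shortest quartile to -0.34 in the longest in the set2 deletion, from -0.20 to -0.49 in H3K36A and from -0.34 to -0.42 in the eaf3 deletion. Because of this shift, log2 ratios of genes and lists are given below relative to the median gene of the same comparison ("relative log2") unless the authors' scale is named. Members of lists are counted as beyond 2-fold on the authors' scale unless the count is given as relative to the median gene. The minimum mean RPKM left out 1669 genes, 555 of them at 10 or more in wild type, so for such genes a lower value in the mutants decided the exclusion. Conversely, 74 genes compared had less than 10 in wild type and were admitted by higher values in the mutants. Several lists are therefore also given over all listed members, relative to the median of all listed genes. Random lists matched on mean RPKM serve as the reference for each gene list.

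**Figure D1:**
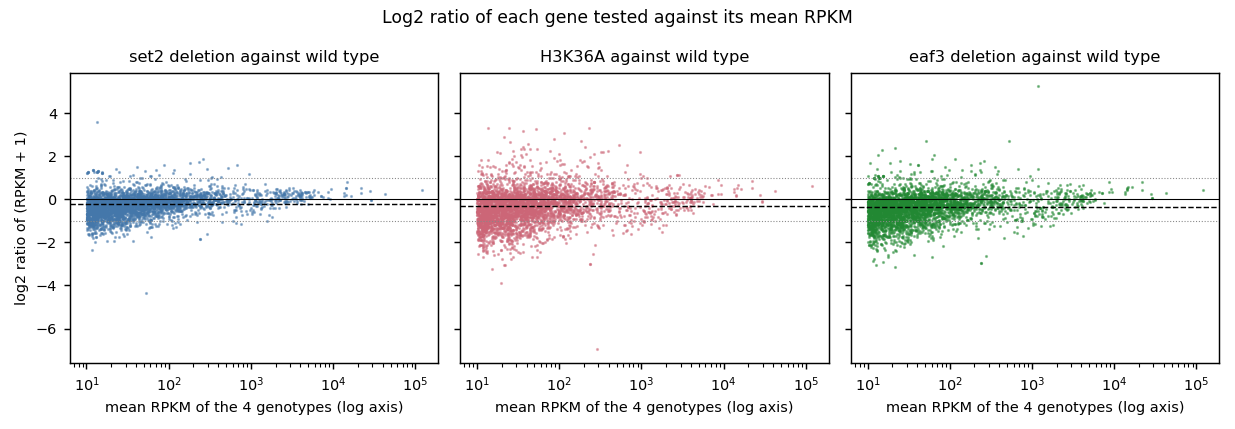
Log2 ratio of RPKM + 1 to wild type (vertical axis) against the mean RPKM of the 4 genotypes (horizontal, log axis) for the 3657 genes compared, 1 panel per mutant and 1 point per gene. Dashed lines mark the median ratios of -0.23, -0.32 and -0.36, and dotted lines mark 2-fold; genes of low mean RPKM lie lower than genes of high mean RPKM.

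Loss of the methyltransferase was compared with wild type first. In the set2 deletion, the medians of the phosphate regulon and of ribosome biogenesis genes lay below nearly all matched lists, and that of stress-induced genes above all of them; 5 of 12, 6 of 19 and 3 of 17 members passed 2-fold. PHO84, the high-affinity phosphate transporter (YML123C, chromosome XIII 24037 to 25800, sacCer3), had an RPKM of 611 in wild type and 197 in the set2 deletion, a relative log2 of -1.40. NOP12 (YOL041C), a nucleolar protein of rRNA processing, had 33.4 against 5.66 (-2.14), and NOC2 (YOR206W), which acts in the maturation of the large ribosomal subunit, 56.2 against 13.9 (-1.72). Genes with higher values included CWP1, HPF1 and TIP1, which encode cell wall mannoproteins: CWP1 (YKL096W, 52.9 against 177), HPF1 (YOL155C, 54.4 against 175) and TIP1 (YBR067C, 279 against 837) were at relative log2 of 1.95, 1.89 and 1.81.

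On the authors' scale, 46 genes were at least 2-fold higher and 235 at least 2-fold lower in the set2 deletion; relative to the median gene the split was 67 to 106, and after quantile normalization it turned, to 92 against 74. A pseudocount of 5 gave 25 and 138, and leaving out genes without a match in the reference gave 28 higher genes. The largest ratio belonged to PUL3 (YNR062C, chromosome XIV 744360 to 745343), a membrane transporter, with an RPKM of 1.13 in wild type and 24.4 in the set2 deletion. PTR2 (YKR093W), the transporter of small peptides, had 84.0 against 306, and the hexose transporter gene HXT4 (YHR092C) 31.9 against 99.1. FCY21 (YER060W), of the purine-cytosine permease family, had 17.0 against 49.8, and YGP1 (YNL160W), which encodes a secreted glycoprotein, 131 against 359. Among the lowest ratios were those of HRP1 (YOL123W), an mRNA cleavage factor, with 92.5 against 23.4, and of ARO10 (YDR380W), a decarboxylase of amino acid breakdown, with 33.6 against 7.73. The metallothionein genes CUP1-1 and CUP1-2, copies in a tandem repeat on chromosome VIII whose rows carry the same values, had 624 against 173, and YHR054C in the same repeat had 46.5 against 11.2. The number of repeat copies in each strain was not measured here. The lowest ratio of all was that of YLR154C-G, with 83.9 against 3.23, which lies in the rDNA on chromosome XII, so residual rRNA reads can enter its value.

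Of the gene lists in the set2 deletion, the phosphate regulon had 5 of 12 members at least 2-fold lower (1 relative to the median gene) and a median relative log2 of -0.66, below all 10000 matched random lists. Besides PHO84, these included VTC3 (93.6 against 41.8), SPL2 (34.1 against 15.2) and PHM6 (23.3 against 10.6). Ribosome biogenesis genes had 6 of 19 at least 2-fold lower (3 relative to the median gene), with a median of -0.24 and 0.03% of matched lists below it. NOP7 (72.5 against 23.1), SOF1 (40.7 against 16.1), NOP56 (238 against 97.8) and CBF5 (141 against 60.1) had the lowest ratios. Genes induced in the environmental stress response had 3 of 17 at least 2-fold higher, with a median of 0.53, above all matched lists. These 3 were GPH1, glycogen phosphorylase (5.13 against 13.9), the cell wall gene SPI1 (73.0 against 166) and the small heat-shock gene HSP12 (28.5 against 61.3). On the authors' scale 11 of the 17 were above wild type and 6 below, with HSP104 the lowest (55.8 against 41.7). Targets of Gcn4, the activator of amino acid biosynthesis, had a median of -0.21 with 0.35% of matched lists below, and 2 of 14 were at least 2-fold lower, ASN1 (400 against 191) and LYS9 (218 against 105), with 0 relative to the median gene. Over all 15 listed members 2.94% of matched lists lay below. Mitochondrial ribosomal protein genes had 0 of 53 beyond 2-fold and a median of 0.13 (-0.10 on the authors' scale), with 99.9% of matched lists below it; over all 65 listed members that share was 88.4%, and 4 were at least 2-fold lower.

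The histone residue was changed in H3K36A, which tests the target of Set2 itself. The phosphate, ribosome biogenesis and stress lists stood apart there too. PHO84 had an RPKM of 3.88 against 611 in wild type (relative log2 -6.65), SPL2 1.36 against 34.1 (-3.58), PHM6 1.60 against 23.3 (-2.91) and VTC3 13.8 against 93.6 (-2.36). Of the stress-induced genes, GPH1 had 59.6 against 5.13 (3.62), hexokinase 1, HXK1, 208 against 29.2 (3.11), and glucokinase, GLK1, 445 against 82.5 (2.74). The ribosome assembly genes PUF6 (5.87 against 56.6), NOC2 (5.90 against 56.2) and RRP1 (7.81 against 59.96) were among the 8 lowest ratios.

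On the authors' scale, 143 genes were at least 2-fold higher and 657 at least 2-fold lower in H3K36A; relative to the median gene the split was 254 to 354, and after quantile normalization 285 to 300. With a mean RPKM of at least 1, 1250 genes were lower. Higher genes also included CWP1 (532 against 52.9), PUL3 (20.2 against 1.13) and HOR7 (250 against 29.0). TAR1 (103 against 9.78) and YLR154W-B (41.9 against 4.72) lie in the rDNA, where residual rRNA reads can enter. YFR052C-A (91.7 against 9.30) overlaps HXK1 and can share its reads. CUP1-1 and CUP1-2 had 77.2 against 624.

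The phosphate regulon in H3K36A had 8 of 12 members at least 2-fold lower (7 relative to the median gene) and a median relative log2 of -1.37, below all matched lists. Ribosome biogenesis had 12 of 19 lower (9 relative to the median gene) and a median of -0.996, also below all of them, led by NOP7 (12.6 against 72.5), DBP3 (16.9 against 73.2), NOP56 (57.4 against 238) and CBF5 (40.6 against 141). Stress-induced genes had 12 of 17 at least 2-fold higher (13 relative to the median gene) and a median of 1.84, above all matched lists, with DDR2 at 57.8 against 8.39. Of these 17, 6 had less than 10 in wild type, DDR2 and GPH1 among them. Over all 20 listed members, 3, 12 and 6 were at least 2-fold higher and 0, 0 and 1 lower in the set2 deletion, H3K36A and the eaf3 deletion, with medians of 0.52, 1.75 and 1.05, above all matched lists. Glucose-repressed genes of carbon metabolism had 4 of 9 at least 2-fold higher (6 relative to the median gene) and a median of 1.29, above all matched lists. The 4 were the hexose transporters HXT7 (685 against 147) and HXT6 (657 against 143), near-identical copies that can share reads, and the citrate cycle enzymes CIT1 (122 against 37.1) and ACO1 (480 against 214). Of the 6 members below the minimum mean, 5 were below wild type in H3K36A, with the gluconeogenic genes PCK1 (1.25 against 8.57) and FBP1 (3.59 against 13.8) at least 2-fold lower. Over all 15, with those 2 lower and 4 higher, the median was 0.91 relative to all listed genes (99.99% of matched lists below). Among the 9 compared, the medians were 0.33 in the set2 deletion (87.9% of matched lists below), where HXT7 passed 2-fold on the authors' scale (300 against 147) and HXT6 also did relative to the median gene (287 against 143), and 0.19 in the eaf3 deletion (53.6%; -0.17 on the authors' scale), where 0 passed on the authors' scale and ADH2 did relative to the median gene (1189 against 643). In the eaf3 deletion 4 of the 6 members left out were at least 2-fold lower. Glycolytic genes had a median of 0.71 in H3K36A (99.8%), with TDH3 at 27275 against 15308 and ADH1 at 10788 against 5890, and 0 of 16 passed 2-fold on the authors' scale against 4 relative to the median gene. Of 10 histone genes in the list, 6 had a row (HTA1, HTA2, HTB1, HTB2, HTZ1 and HHO1), and none of these encodes H3 or H4. These 6 had 2 at least 2-fold higher, HTB2 (1448 against 648) and HTA1 (1581 against 740), against 3 relative to the median gene, and a median of 1.00 (99.5%). Their medians were 0.49 in the set2 deletion (96.9%) and 0.60 in the eaf3 deletion (95.6%), with none beyond 2-fold. Genes of sulfur and methionine metabolism had a median of 0.58 in H3K36A (98.8%), with 1 of 8 beyond 2-fold, MMP1 (17.5 against 45.9, lower); relative to the median gene 1 was also higher. Gcn4 targets went both ways in H3K36A, with ARG1 at 89.3 against 30.4, LYS9 at 68.0 against 218 and ASN1 at 140 against 400, 1 higher and 2 lower (2 and 2 relative to the median gene), and a median of 0.25 (-0.06 on the authors' scale; 68.8%).

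In the eaf3 deletion, which removes the chromodomain protein, the largest ratio of any gene and genotype on the higher side was that of SOP4 (YJL192C, chromosome X 72710 to 73414), a gene of the endoplasmic reticulum, with an RPKM of 4353 against 114 in wild type, 105 in the set2 deletion and 123 in H3K36A. Its neighbours had no such value: RPS14B had 600 against 696, and YJL193W 18.2 against 16.5. The 5 MATa-specific genes compared were each at least 2-fold lower, among them BAR1, the protease that degrades alpha-factor (12.4 against 84.6, relative log2 -2.32), AGA2, a subunit of a-agglutinin (22.1 against 102, -1.80), and STE2, the alpha-factor receptor (179 against 418, -0.86). The oxidative phosphorylation list lay below all matched lists, with 8 of 21 members at least 2-fold lower, and ENO1 of glycolysis was higher (1864 against 702).

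On the authors' scale, 56 genes were at least 2-fold higher and 585 at least 2-fold lower in the eaf3 deletion; relative to the median gene the split was 130 to 257, and after quantile normalization 163 to 197. With a mean RPKM of at least 1, 1220 genes were lower. The acid phosphatase gene PHO5 (YBR093C, chromosome II 429548 to 430951) had 158 against 37.4, PMA2 (YPL036W), a plasma membrane proton pump, 40.4 against 7.50, and YGP1 872 against 131. The lower side held ARO10 (3.22 against 33.6), NOP12 (3.65 against 33.4), and CUP1-1 and CUP1-2 (78.6 against 624). COS8 (YHL048W, chromosome VIII 6401 to 7546), near a chromosome end, had 2.5 against 21.6. YAR068W on chromosome I (2.22 against 23.2) and YHR214W (1.59 against 16.8) and YHR214W-A (2.81 against 32.7) on chromosome VIII belong to a pair of near-identical subtelomeric regions, so their reads may be shared.

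All 5 MATa-specific genes compared were at least 2-fold lower in the eaf3 deletion (3 relative to the median gene), with a median relative log2 of -1.73, below all matched lists; STE6, the a-factor exporter, was the member at least 2-fold lower in each of the other mutants too on the authors' scale (55.0 in wild type, 26.1 in the set2 deletion, 17.9 in H3K36A, 12.2 in the eaf3 deletion). The list median was 0.06 in the set2 deletion (-0.16 on the authors' scale; 42.1% of matched lists below) and 0.48 in H3K36A (85.2%). SAG1, the MATalpha-specific gene with a mean above 10, had 12.5 in wild type and 12.3, 18.4 and 11.4 in the set2 deletion, H3K36A and the eaf3 deletion. Oxidative phosphorylation genes had 8 of 21 at least 2-fold lower in the eaf3 deletion (2 relative to the median gene) and a median of -0.49, below all matched lists, with QCR6 (31.4 against 94.1), COX6 (17.0 against 47.0), ATP3 (37.0 against 95.5) and COX12 (19.2 against 46.7). The same list had medians of 0.24 in the set2 deletion (96.3%) and 0.35 in H3K36A (89.5%). Glycolytic genes had 1 of 16 at least 2-fold higher in the eaf3 deletion (5 relative to the median gene) and a median of 0.83, above all matched lists, against 0.33 in the set2 deletion (49.6%). Ribosome biogenesis had 9 of 19 at least 2-fold lower (4 relative to the median gene), with a median of -0.48 and 0.01% of matched lists below it. Stress-induced genes had 6 of 17 at least 2-fold higher (10 relative to the median gene), with a median of 1.07, above all matched lists. On the authors' scale 12 of these were above wild type and 5 below, with HSP104 the lowest (35.1 against 55.8). The phosphate regulon had a median of -0.03 (25.9%), with PHO5 higher and PHO3, another acid phosphatase, lower (146 against 378).

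**Figure D2:**
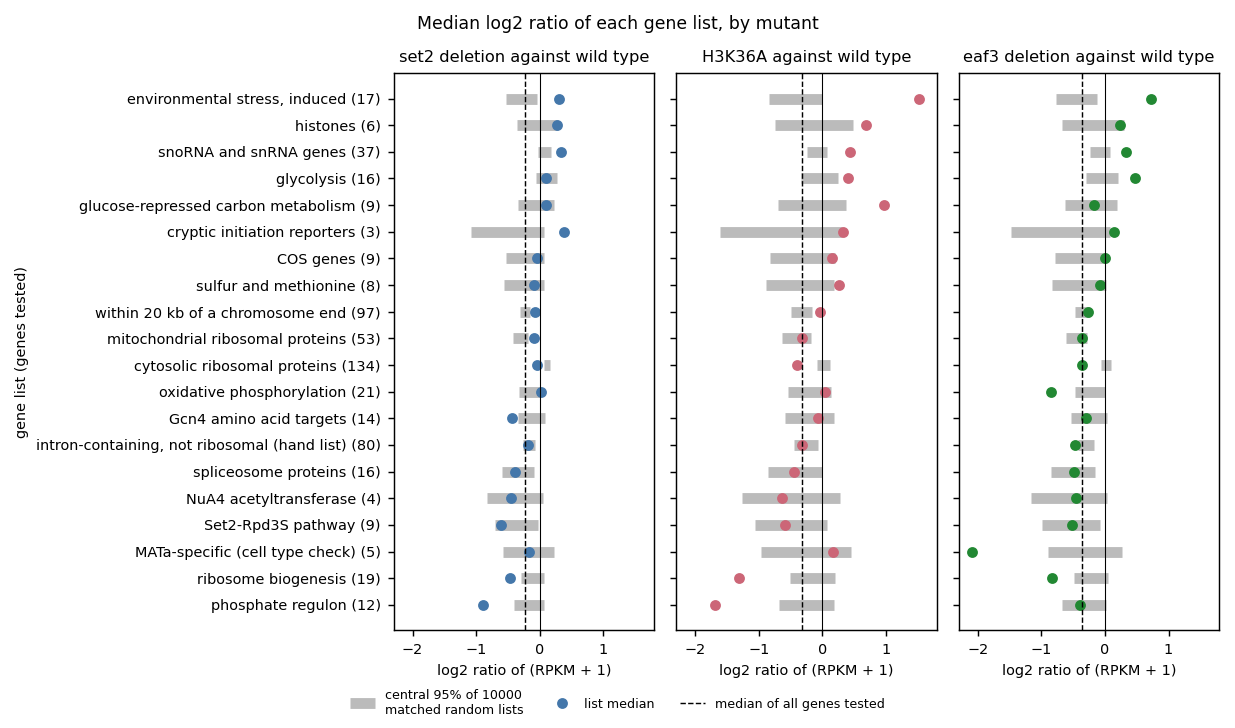
Median log2 ratio of RPKM + 1 to wild type on the authors' scale (horizontal axis) for each gene list (vertical axis, genes compared in parentheses), 1 panel per mutant. Points are list medians, grey bars the central 95% of 10000 random lists matched on mean RPKM, dashed lines the median of all genes compared; stress-induced genes lie above the bars and ribosome biogenesis genes below them in each panel.

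The study concerned spliceosome assembly, so genes with introns were examined as a group. RPKM per gene does not separate spliced from unspliced RNA, and splicing itself was not measured by these values. A list of 95 intron-containing genes outside the ribosomal protein families was made by hand and not taken from an annotation, and 80 were compared. Of these 80, 1 was at least 2-fold higher and 8 at least 2-fold lower in the set2 deletion. The counts were 2 and 17 in H3K36A, and 0 and 18 in the eaf3 deletion. Relative to the median gene these counts were 1 and 2, 3 and 8, and 2 and 7. Among all genes compared, 6.43%, 18.0% and 16.0% were at least 2-fold lower on the authors' scale, in the same order of mutants. The list median was 0.03 in the set2 deletion (-0.19 on the authors' scale; 36.2% of matched lists below), -0.01 in H3K36A (-0.33; 20.5%) and -0.11 in the eaf3 deletion (-0.47; 0.47%). Compared directly, the list had a median relative log2 of -0.08 in the eaf3 deletion against the set2 deletion (0.23% of matched lists below) and of -0.09 against H3K36A (1.42%). LSM7 (33.7 in wild type, 12.3, 8.87 and 8.54 in the set2 deletion, H3K36A and the eaf3 deletion) and LSM2 (69.0, 28.5, 21.2 and 16.5), of the Lsm ring that binds U6 snRNA and mRNA ends, had the lowest ratios together with the prefoldin subunit gene GIM5 (40.1, 16.9, 11.6 and 11.8). COX5B, an isoform of a cytochrome oxidase subunit, was higher in each mutant (14.2 in wild type, 30.8, 62.7 and 27.9 in the set2 deletion, H3K36A and the eaf3 deletion). The 16 genes of spliceosome proteins compared had medians of -0.17, -0.13 and -0.12, with 25.1%, 45.2% and 41.6% of matched lists below, and 2 passed 2-fold in H3K36A (0 relative to the median gene): BRR2, the U5 helicase (8.31 against 19.6), and STO1, of the cap-binding complex (22.5 against 50.6). The 19 members below the minimum mean lay lower, with 5, 10 and 9 at least 2-fold lower on the authors' scale, among them PRP39 of the U1 snRNP (13.1 in wild type, 5.32, 3.10 and 2.78 in the mutants). The minimum mean itself tends to leave out genes with lower values in the mutants, so these counts alone do not set the list apart. Over all 35 listed members the medians relative to all listed genes were -0.29, -0.39 and -0.28, with 9.30%, 7.71% and 21.6% of matched lists below. Over the 94 genes of the hand-made intron list that have a row, the medians were 0.05, 0.08 and -0.01 (21.5%, 30.2% and 1.86%).

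The 134 cytosolic ribosomal protein genes, many of which hold introns, depend on the reference used. Relative to the median gene their medians were 0.18 in the set2 deletion, -0.08 in H3K36A and -0.002 in the eaf3 deletion, and on the authors' scale -0.05, -0.39 and -0.36. Each of the 3 medians lay below all 10000 lists matched on mean RPKM, with and without small RNA genes among the matched genes. Members at least 2-fold lower numbered 3, 18 and 11 (0, 6 and 3 relative to the median gene), among them RPL39 (1216 in wild type against 563, 456 and 407), RPL38 (865 against 417, 272 and 252) and RPS30A (1097 against 542, 374 and 385). On the authors' scale these are smaller shares than the 6.43%, 18.0% and 16.0% of all genes compared that were at least 2-fold lower. The 37 small nuclear and nucleolar RNA genes had medians of 0.56, 0.75 and 0.69, each above all matched lists, with snR49 beyond 2-fold in H3K36A (4042 against 1836); relative to the median gene 0, 3 and 2 passed.

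Genes of the Set2 and Rpd3S pathway had medians of -0.38, -0.27 and -0.17 (7.25%, 32.6% and 40.2% of matched lists below), with ISW1, a chromatin remodeller (31.0 in wild type, 12.8 in H3K36A and 14.8 in the eaf3 deletion), and SPT6, a histone chaperone (47.6 and, in H3K36A, 20.0), beyond 2-fold among 9 on the authors' scale and neither relative to the median gene. Over all 13 listed members the shares were 4.69%, 39.6% and 21.9%. The 4 genes of the NuA4 acetyltransferase, of which Eaf3 is also a subunit, had medians of -0.22, -0.32 and -0.10 (36.1%, 36.5% and 59.6%), and EAF6 passed 2-fold in H3K36A (7.53 against 18.7) and the eaf3 deletion (7.10) on the authors' scale. Over all 9 listed NuA4 genes, 3, 5 and 5 were at least 2-fold lower, with 4.56%, 5.26% and 2.12% of matched lists below the median. Of genes with known internal promoters that fire in set2 mutants, 3 were compared: PCA1 was higher in each mutant (10.6 in wild type, 30.1, 25.9 and 23.9), SPB4 lower (23.7, 9.80, 8.11 and 10.3), and STE11 had 9.54, 12.7, 12.3 and 10.7. Their median, which is the value of STE11, was 0.61, 0.65 and 0.51 (99.6%, 97.9% and 98.2% of matched lists below). STE11 had less than 10 in wild type and was admitted by higher values in the mutants. The list median turned negative when genes with a mean RPKM of at least 1 were admitted, with shares of 47.6%, 44.2% and 31.9% over all 5 listed. RPKM per gene does not separate internal from full-length transcripts. The 97 genes within 20 kb of a chromosome end had medians of 0.16 (-0.07 on the authors' scale; 99.98% of matched lists below), 0.28 (-0.04; 99.99%) and 0.09 (-0.27; 91.3%); over all 158 listed the shares were 100%, 100% and 99.7%. The 9 COS genes had medians of 0.18 (-0.05; 87.0%), 0.47 (96.2%) and 0.36 (96.2%); over all 10 listed the shares were 98.3%, 98.9% and 98.97%. The sulfur list had medians of 0.13 in the set2 deletion (-0.09; 82.1%) and 0.28 in the eaf3 deletion (-0.07; 93.6%; 99.2% over all 12 listed), the Gcn4 list 0.06 in the eaf3 deletion (-0.30; 35.7%), and mitochondrial ribosomal proteins -0.004 in H3K36A (77.3%) and -0.006 in the eaf3 deletion (82.3%). Over all 65 listed mitochondrial ribosomal protein genes, 16 were at least 2-fold lower in each of these 2 mutants, with shares of 67.6% and 26.4%. Lists with fewer than 3 genes compared were the galactose regulon (GAL80, 65.4, 61.1, 52.6 and 53.5; GCY1, 15.1, 12.9, 14.5 and 10.5), meiosis (REC107, 16.3, 14.5, 16.3 and 14.2) and the auxotrophic markers (HIS3, 61.2, 72.1, 141 and 69.4, beyond 2-fold in H3K36A alone). No seripauperin gene reached a mean of 10; for the 5 listed the shares were 97.9%, 98.4% and 80.9%.

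The mutants were compared with each other directly, since Eaf3 reads the residue that Set2 methylates. In H3K36A against the set2 deletion, the phosphate genes PHO84 (3.88 against 197), SPL2 (1.36 against 15.2) and PHM6 (1.60 against 10.6) were lower, as were URA1, dihydroorotate dehydrogenase (YKL216W, 43.5 against 293), and MDH2, a malate dehydrogenase (13.2 against 66.0). ARG1 (89.3 against 15.4), DDR2 (57.8 against 10.8), HXK1 (208 against 48.3) and the vacuolar aminopeptidase gene APE1 (63.9 against 14.3) were higher. In the eaf3 deletion against the set2 deletion, SOP4, PMA2, PHO5 and TIS11, an mRNA-binding protein gene (24.1 against 5.49), were higher, while COS8 (2.5 against 26.1), BAR1 (12.4 against 71.7) and the YHR214W, YHR214W-A and YAR068W group were lower. YLR154C-G in the rDNA, at 108 against 3.23, was also higher there. In the eaf3 deletion against H3K36A, PHO84 (344 against 3.88), SPL2 (27.0 against 1.36), PHM6 (25.6 against 1.60), URA1 (426 against 43.5) and SOP4 were higher, and IMD2, IMP dehydrogenase (14.6 against 135), ARG1 (12.3 against 89.3) and COS8 were lower.

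On the authors' scale, 14 genes were at least 2-fold higher and 48 lower in the eaf3 deletion against the set2 deletion (24 and 29 relative to the median gene), 85 and 48 in H3K36A against the set2 deletion (97 and 29), and 29 and 111 in the eaf3 deletion against H3K36A (29 and 103). The median log2 ratios of these 3 comparisons were -0.14, -0.11 and -0.03. The stress-induced list was higher in H3K36A than in the set2 deletion by a median relative log2 of 1.30, above all matched lists, and the ribosome biogenesis and phosphate lists lower, at -0.54 and -0.72, below all of them. Against the set2 deletion, the eaf3 deletion had a median of -0.69 for oxidative phosphorylation and -1.72 for MATa-specific genes, each below all matched lists, and of 0.68 for the phosphate regulon, above all of them.

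**Figure D3:**
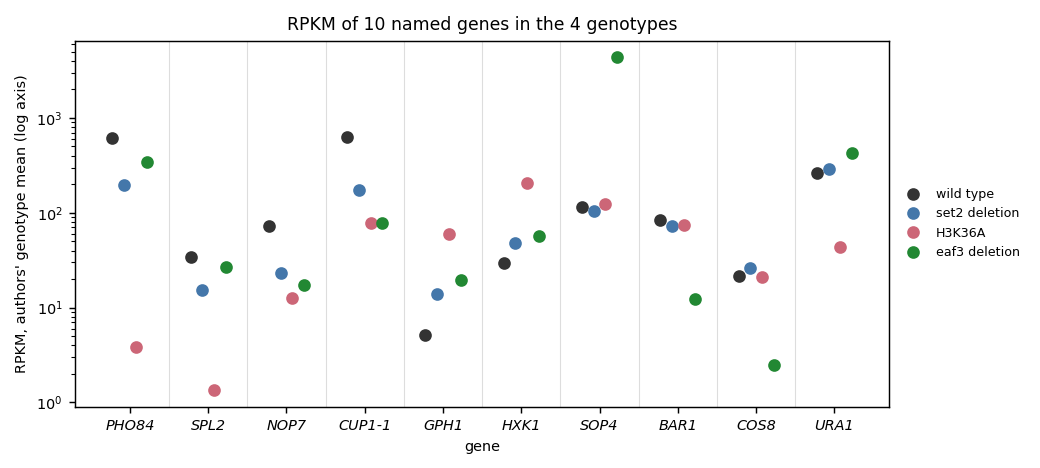
RPKM (vertical, log axis) of 10 genes (horizontal axis) in wild type, the set2 deletion, H3K36A and the eaf3 deletion, 1 point per genotype for the authors' mean of 2 libraries. PHO84 runs from 611 in wild type to 3.88 in H3K36A, and SOP4 from 114 in wild type to 4353 in the eaf3 deletion.

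The 3 mutants were then compared for genes that moved together. At least 2-fold higher in all 3 were 18 genes, and 218 were at least 2-fold lower in all 3. Independent lists of these sizes would share 0.028 and 6.75. Unchanged groups simulated against the same wild-type values shared 0.09 and 0.17 genes beyond 2-fold, and 3.58 and 74.8 when as many genes were taken from each simulated mutant as were observed (at most 8 and 98 in 100 draws). Relative to the median gene the observed counts were 35 and 95, and after quantile normalization 70 and 63. The higher genes included PUL3 (7.91 in the eaf3 deletion), CWP1 (173), YGP1, GPH1 (19.8), HOR7 (75 in the set2 deletion and 107 in the eaf3 deletion), PTR2 (370 in H3K36A and 287 in the eaf3 deletion), HPF1 (363 and 136) and TAR1 in the rDNA (25.6 in the set2 deletion and 69.2 in the eaf3 deletion). Among the lowest were NOP12, NOC2 (10.2 in the eaf3 deletion), PUF6 (15.8 in the set2 deletion and 9.84 in the eaf3 deletion), ARO10, HRP1 (15.9 in H3K36A and 14.5 in the eaf3 deletion), CUP1-1, CUP1-2 and YHR054C (7.11 and 6.87). The set2 deletion and H3K36A shared 23 higher and 227 lower genes, against 1.8 and 42.2 for independent lists and 13.7 and 124 for simulated lists of the same sizes with the wild type in common (at most 23 and 144). The 23 higher genes of this pair were thus reached by unchanged groups. For the set2 and eaf3 deletions the counts were 26 and 226, against 0.70 and 37.6 and against 7.52 and 116 (at most 14 and 138). H3K36A and the eaf3 deletion shared 32 and 464, against 2.19 and 105 and against 15.6 and 251 (at most 23 and 277). Across the 3657 genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.85, 0.84 and 0.81 for these pairs, and unchanged groups simulated against the same wild-type values gave 0.50 for each pair. The covariances were 0.32, 0.26 and 0.40, against 0.06 simulated. The wild-type libraries are common to every pair and could not be split, so part or all of the excess may come from them. The simulation cannot tell how much, because it assumes the same noise in wild type as in the mutants. It also holds no shift of the median.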

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

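No paired analysis was possible because the table holds an average per genotype and its columns carry no replicate number. For the same reason the alternatives that need single libraries were not run: the replicate block, fits of 4 libraries, the fit without a trend, a 1.5-fold minimum with an adjusted p, leaving out each library, and camera with an estimated correlation. A second intron list from an annotation was not run either. A setting with no filter would add no gene to the setting with a mean RPKM of at least 1, since every gene listed is at 1 or more. The 2 alternatives that leave out rows were chosen after seeing the data, as was the choice to give list medians relative to the median gene. Unknown depth and the missing spread between libraries limit every value. The counts of genes beyond 2-fold stayed within 1.5 times with a pseudocount of 0.1, without small RNA genes and without rows of repeated values.

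Centring on the median gene gave 106 lower genes in the set2 deletion, 254 higher and 354 lower in H3K36A, 130 and 257 in the eaf3 deletion, 24 and 29 in eaf3 against set2, 29 lower in H3K36A against set2, and 35 higher and 95 lower in all 3. Quantile normalization gave 92 and 74 in the set2 deletion, 285 and 300 in H3K36A, 163 and 197 in the eaf3 deletion, 23 and 29 in eaf3 against set2, 29 lower in H3K36A against set2, and 70 and 63 in all 3. Both remove the shift of the median by construction. A mean RPKM of at least 1, which admits more genes, gave 606, 1250 and 1220 lower genes in the 3 mutants and 559 in all 3; the internal promoter list in each mutant and the Gcn4 and mitochondrial ribosomal protein lists in the set2 deletion then lay inside the central 95% of matched lists, and the COS list in each mutant and the NuA4, sulfur and chromosome-end lists in the eaf3 deletion outside it. A pseudocount of 5, which shrinks ratios of low values, gave 25 higher and 138 lower genes in the set2 deletion, 28 lower in eaf3 against set2, 24 lower in H3K36A against set2 and 130 lower in all 3. Without rows lacking a match in the reference, 28 genes were higher in the set2 deletion.

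Several list medians changed sign. That of cytosolic ribosomal proteins became 0.0064 in the eaf3 deletion with a pseudocount of 0.1, 0.012 without small RNA genes, 0.0029 without rows of repeated values, 0.0049 without unmatched rows and 0.12 with a mean of at least 1, where H3K36A gave 0.053; in the set2 deletion it was -0.046 on the authors' scale and -0.12 after quantile normalization. The internal promoter list became -0.21, -0.29 and -0.38 in the set2 deletion, H3K36A and the eaf3 deletion with a mean of at least 1. On the authors' scale, chromosome-end genes were at -0.069 in the set2 deletion, -0.041 in H3K36A and -0.27 in the eaf3 deletion, and mitochondrial ribosomal proteins at -0.10 in the set2 deletion. Several other lists, the COS and sulfur lists in the set2 deletion among them, also changed sign between the scales, and both values are given above. The intron-containing genes moved to -0.19, -0.33 and -0.47 on the authors' scale and to -0.085 in the set2 deletion after quantile normalization; of these only the set2 deletion had a positive median relative to the median gene (0.03). Apart from what the settings do by construction, the cause was not tested.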

Other observations

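The proteasome list and the tests on copies of the CUP1 repeat, on a uniform background and on growth were chosen after the results, or part of the values they use, were seen; the other tests were written before the values they measure, but after the pattern each addresses had been seen.

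The proteasome list had a lower median than its matched lists in each mutant. Of 31 genes for its subunits, 8 were at least 2-fold lower in the set2 deletion, 15 in H3K36A and 17 in the eaf3 deletion, and none was 2-fold higher. The list's median relative log2 was -0.55, -0.68 and -0.70, below all 10000 lists matched on mean RPKM in each mutant, and 7 members in each mutant, 5 of them the same in all 3, stayed at least 2-fold lower relative to the median gene. RPN8 had an RPKM of 29.5 in wild type, 8.78 in the set2 deletion, 11.0 in H3K36A and 8.44 in the eaf3 deletion, RPN12 66.4, 24.1, 22.4 and 17.3, and RPT2 64.1, 25.6, 16.7 and 17.4. PRE3, of the catalytic core, had 176, 155, 168 and 144. RPN4, the transcriptional activator of these genes, had 23.7, 11.6, 9.49 and 9.02.

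The rows for HMLALPHA2 and MATALPHA2, of the alpha information, carry equal values. These were 8.97 in wild type, 3.17 in the set2 deletion, 2.62 in H3K36A and 2.65 in the eaf3 deletion. The a-factor gene MFA2 had 73.9, 125, 98.6 and 33.7 in the same order. Neither alpha row was thus higher in the eaf3 deletion, where MATa-specific genes were lower. How reads that map to several places were treated is unknown, so these rows need not measure the silent copy. An alpha gene below the table's lowest value in wild type would have no row, even if higher in a mutant. Whether silent alpha information was expressed in the eaf3 deletion therefore cannot be decided here. SOP4 stood at 4353 in the eaf3 deletion alone among its neighbours, and no explanation was tested.

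The ribosome biogenesis list lay below nearly all matched lists in all 3 mutants. Dependence of the ratio on expression level and gene length does not account for it, since at most 0.03% of random lists matched on both had a lower median in any mutant. A uniform background in the wild-type libraries is argued against as well: it would have to reach 73.7 RPKM for the values of H3K36A, 34.3 for the set2 deletion and 41.0 for the eaf3 deletion, and 79.0%, 61.7% and 66.0% of listed genes lie below that in wild type. Slower or later growth of the mutant cultures stays open: 0.0% of matched lists lay below the ribosomal protein median in each mutant, and the stress-induced list lay above all of its matched lists, although ribosomal proteins were at 0.18 relative to the median gene in the set2 deletion. Of the 17 stress-induced genes, 6 in the set2 deletion and 5 in the eaf3 deletion were below wild type on the authors' scale. The density of each culture is not given in the sources used here, and a direct effect of the genotypes was not tested.

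CUP1-1 and CUP1-2 were lower in all 3 mutants. Lower activation by the copper-responsive factor Cup2 was to be judged on its targets CRS5 and SOD1, but CRS5 has no row. SOD1 did not fall with CUP1: its relative log2 was at least 0.35 in each mutant. On the authors' scale it was at 0.17 in the set2 deletion, 0.99 in H3K36A and -0.008 in the eaf3 deletion. That gene alone does not decide the question. Fewer copies of the CUP1 repeat stay open: of 2 other genes of the repeat, YHR054C, which shares sequence with RSC30 (34.6 in wild type and 13.96, 9.54 and 9.77 in the mutants), lay at most 0.45 log2 above CUP1 in any mutant and YHR052W-A up to 0.59, more than the 0.5 set as the limit for a common change. YHR052W-A is low (15 in wild type, 2.02 in H3K36A and 2.08 in the eaf3 deletion), and without the pseudocount its excess was at most 0.14. Copy number was not measured here.

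URA1 was lower in H3K36A (43.5 against 261 in wild type). A general drop of pyrimidine genes is argued against, since URA2, URA5, URA6 and URA7 had a median relative log2 of 0.04. Less activation by Ppr1, which controls URA1 and URA4, is a candidate explanation: URA4 was at -0.80 in H3K36A, against 0.26 in the set2 deletion and 1.01 in the eaf3 deletion. HIS3, the marker gene compared, was at least 2-fold higher in H3K36A alone (141 against 61.2), but as it is also a Gcn4 target this does not settle a difference in markers. Whether the strains carry different uracil markers or plasmids is not given for each genotype in the sources used here.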
